A study of Homo sapiens with 9 samples.

How the data were processed

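RNA sequencing was analysed for 9 libraries of A549 cells, 3 each with a control, a HES1-directed or a HES4-directed short hairpin RNA, grouped by the sample titles and the hairpin named in the labels. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made from total RNA with a SMARTer RNA-seq kit. The authors deposited 1 table of estimated counts per gene with 60664 Ensembl human gene identifiers; the aligner, the counter and the annotation are not given in the sources used here. The submitters' processing notes name the mouse builds GRCm38 and mm10, which do not match the human identifiers, so no build is taken from them. Of the nonzero values 35.5% were not whole (tolerance 1e-06), as estimated counts are where a counter shares reads between genes, and the table carries 2 decimals. Whether counting used strand is not given, so a gene and an antisense or overlapping neighbour cannot be told apart, and near-identical copies such as histone and ribosomal protein genes are uncertain. Names came from the reference table for 60463 of the identifiers, which hold 99.92% of the counts. Coordinates, exon numbers, transcript lengths and GC contents are from GENCODE release 29 on GRCh38.

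From the deposited estimated counts, values were rounded to whole numbers. Genes were kept by edgeR's filterByExpr, which left 16903, 1501 of them without a symbol. Libraries were scaled by TMM factors, and the 3 groups were fitted together with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood negative binomial model, 6 residual degrees of freedom, common biological coefficient of variation 0.0403). Each comparison was tested with the quasi-likelihood F test and Benjamini-Hochberg adjustment, at an adjusted p of 0.05. Adjusted p without another name are of this test. The standard error of a log2 fold change is its size divided by the square root of F. CPM are counts scaled to one common library size with the TMM factors, with the SD over 3 libraries. Totals of 22.8 to 27.6 M counts limit precision most for genes with few counts, and a count of 0 in a group was bounded by a floor of 3 counts over the group. Floors and counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

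Gene lists, 37 in number, were written before the data were examined, and 36 had at least 5 tested members; the list of erythroid markers had 0 of 9. They were tested on log2 CPM (prior count 2) with limma's camera at a preset correlation of 0.01, adjusted over 108 tests. Ranges of camera's adjusted p over alternatives leave out the estimated correlation and fry. Camera with an estimated correlation and fry were run beside it. A call lost with an estimated correlation need not mean a larger correlation, since some estimates lay below the preset (0.00939 for hypoxia and glycolysis genes). Other estimates lay far above it, at 0.736 for ribosomal protein, 0.671 for mitochondrially encoded and 0.434 for oxidative phosphorylation genes. They were 0.340 for leukocyte markers and 0.274 for mesenchymal genes. For these 5 lists the preset understates the correlation, and their calls with it are weak. With the preset correlation 13, 16 and 14 lists were called in shHES1 against shCtrl, shHES4 against shCtrl and shHES1 against shHES4. With an estimated correlation 3, 3 and 2 were called: interferon response, G1/S and NF-kB genes in shHES1, interferon response, p53 target and hypoxia genes in shHES4, and interferon response and hypoxia genes in the direct comparison. DDX58 in the lists was matched to its current symbol RIGI.

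Named genes followed a rule set before the data were examined. It takes the HES and HEY family; the 12 largest rises and 12 largest falls per shHES group against shCtrl, and 6 of each in the direct comparison, among genes with an adjusted p under 0.05, a mean of at least 5 CPM, a named symbol and no overlap of the groups; the 5 and 5 genes with the largest smaller change in both shHES groups; and up to 4 members with the smallest adjusted p per list described. CDKN2A, IRS4 and ISG15 and further list members were named after their values were seen. Some members of the lists are not reported here by name.

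The fit was tested on simulated counts with the means and library sizes of these data. For shHES1 against shCtrl, over 16685 simulated genes, 60% of genes changed 1.25-fold, 64% at 1.5-fold, 86% at 2-fold and 98% at 4-fold were recovered, with 9 false calls. For shHES4 against shCtrl, over the same number of genes, the shares were 48%, 66%, 66% and 94%, with 10 false calls. Replicates were compared by chi-square per degree of freedom over genes with at least 20 counts: pairs within a group gave 2.31 to 6.36 and pairs between groups 5.84 to 12.3, so no 2 libraries agreed within sampling noise. Both within-group values above 3.18 were those of shCtrl replicate 3, at 4.81 and 6.36, and this library also had the highest share of mitochondrial counts (7.16%) and the lowest of ribosomal protein counts (4.07%). By this measure shCtrl replicate 1 was nearer to shHES4 replicates 1, 2 and 3 (6.21, 5.84 and 6.12) than to shCtrl replicate 3 (6.36). By the median chi-square over genes it was slightly nearer to shCtrl replicate 3 (1.30 against 1.43, 1.32 and 1.32). Alternatives planned beforehand were edgeR with DESeq2's size factors, total counts only, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter, a filter at a mean of 5 CPM, a fit of the 6 libraries compared, the replicate number as a block, and leaving out each library. A correction for GC content and transcript length (smooth trends fitted with mgcv 1.9.3) and thinning to equal depth were added after seeing the data.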

Results

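Gene expression was measured by RNA sequencing in A549 cells, an established human lung adenocarcinoma line. The 9 libraries formed 3 groups of 3, carrying a control short hairpin RNA (shCtrl) or a hairpin directed, per the labels, at HES1 (shHES1) or at HES4 (shHES4). A short hairpin RNA is processed in the cell into a small RNA that lowers the transcript it matches. HES1 and HES4 encode basic helix-loop-helix transcriptional repressors of the hairy and enhancer of split family, and HES1 is a classical target of Notch signalling. The series title gives the question as the effect of both factors on gene expression in this line. Total counts were 26.4, 23.9 and 24.4 M in the shCtrl libraries, 27.6, 25.6 and 26.3 M in shHES1, and 22.8, 22.8 and 24.4 M in shHES4, and 16903 genes were tested. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

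The targeted genes were examined first. HES1 (ENSG00000114315) lies on chromosome 3 from 194136145 to 194138732 on the plus strand of GRCh38, and HES4 (ENSG00000188290) on chromosome 1 from 998962 to 1000172 on the minus strand. Both are protein-coding genes whose first listed transcript in GENCODE release 29 has 4 exons. HES1 was not lower in the libraries labelled shHES1, where it stood at 9.11, 6.40 and 8.32 CPM (counts normalised for library size), against 6.99, 6.55 and 7.17 CPM in shCtrl. The means were 7.94 ± 1.40 and 6.90 ± 0.320 CPM (SD, n = 3), a log2 fold change of 0.20 ± 0.12 (SE) with an adjusted p of 0.345 in edgeR's quasi-likelihood test. In the libraries labelled shHES4, HES1 read 6.42, 6.80 and 7.01 CPM, with a log2 fold change of -0.03 ± 0.12 and an adjusted p of 0.929. HES4 was lower in both shHES groups. It read 21.3, 25.4 and 27.7 CPM in shCtrl, 20.4, 17.1 and 16.6 CPM in the libraries labelled shHES4, and 18.3, 15.2 and 15.7 CPM in those labelled shHES1. The log2 fold change of HES4 was -0.46 ± 0.10 in shHES4 (edgeR adjusted p = 0.00992) and -0.59 ± 0.10 in shHES1 (edgeR adjusted p = 7.60e-04). The 2 shHES groups did not differ detectably from each other in HES4, with a log2 difference of -0.13 ± 0.10 and an edgeR adjusted p of 0.456. The call for HES4 in shHES4 ended without shHES4 replicate 2 (adjusted p = 0.0549) and without shHES4 replicate 3 (adjusted p = 0.0619), and over all alternatives its adjusted p ran from 1.30e-07 to 0.0619. HES4 has a GC content of 73.9%, and after a correction for GC content and length, chosen after seeing the data, it stood at -0.31 ± 0.07 in shHES4 and -0.51 ± 0.07 in shHES1. Because HES1 goes against its label, the groups are named by their labels throughout, shHES1 and shHES4 together as the shHES groups, and each direction given for shHES1 is that of the libraries labelled shHES1.

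**Figure D1:**
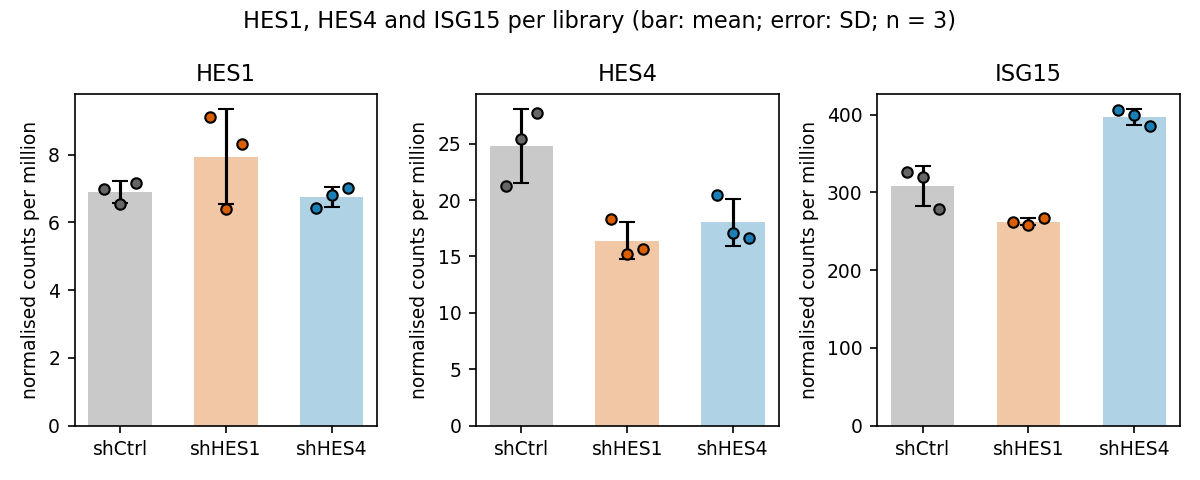
Normalised counts (CPM) of HES1, HES4 and ISG15 in each library (points), with the group mean (bar) and SD (error bar), n = 3 per group. HES1 averaged 7.94 CPM in shHES1 and 6.90 CPM in shCtrl, while HES4 averaged 24.8 CPM in shCtrl, 16.4 CPM in shHES1 and 18.0 CPM in shHES4; ISG15, the gene next to HES4, averaged 308 CPM in shCtrl, 262 CPM in shHES1 and 397 CPM in shHES4.

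Among the other family members, HES2, HES6, HES7, HEY1 and HEYL were tested and none was called in either shHES group. The largest estimates were those of HES7 in shHES1, at 0.56 ± 0.29 with an adjusted p of 0.267, and of HES6 in shHES1, at -0.30 ± 0.13 with an adjusted p of 0.190. HES5 had 0 counts in the 9 libraries, and HES3 and HEY2 were too low to test. Of 30 tested Notch receptors, ligands and regulators, 3 were higher and 1 lower in shHES1, also when adjusted over the list alone. The ligand gene JAG2 rose by 0.27 ± 0.05 and the coactivator gene MAML2 by 0.48 ± 0.12, and the receptor gene NOTCH1 fell by 0.30 ± 0.05 on the log2 scale. The call for MAML2 ended without shCtrl replicate 1 or 2 or shHES1 replicate 1 or 2 (adjusted p = 0.0549, 0.0538, 0.0596 and 0.0666). In shHES4, NUMBL fell by 0.64 ± 0.12 and SPEN by 0.15 ± 0.04, and no other member of the list was called. The call for SPEN ended without shCtrl replicate 2 or 3, shHES1 replicate 1 or shHES4 replicate 1, 2 or 3 (adjusted p = 0.0759, 0.115, 0.0558, 0.0957, 0.0844 and 0.0815), with the 6 libraries compared alone (0.0654) and with the replicate number as a block (0.0544). It also ended after the GC and length correction, where it shrank to -0.09 ± 0.04 (adjusted p = 0.131). The list as a whole was not called in shHES1 (camera adjusted p = 0.410, where its median was 0.02 and its mean -0.00308) or in shHES4 (camera adjusted p = 0.530, where its median was 0.01 and its mean -0.06).

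The libraries labelled shHES1 were then compared with shCtrl. GPR141, an orphan G protein-coupled receptor gene, rose by 1.81 ± 0.11 on the log2 scale, from 4.94 ± 0.744 to 17.4 ± 0.477 CPM (SD, n = 3). CA9, the hypoxia-induced carbonic anhydrase, rose by 1.60 ± 0.12, and NTRK2, the receptor for brain-derived neurotrophic factor, by 1.51 ± 0.11. The secreted Wnt inhibitor gene WIF1 rose by 1.43 ± 0.14. The matrix genes LOX, MMP2, COL6A2 and PXDN rose by 1.33 ± 0.13, 1.28 ± 0.13, 1.26 ± 0.14 and 1.24 ± 0.07. The interleukin receptor gene IL7R rose by 1.30 ± 0.12, the mannosidase gene MAN1A1 by 1.25 ± 0.05 and the hyaluronan-binding gene CEMIP by 1.21 ± 0.09. NDRG1, a stress and hypoxia-responsive gene, went from 68.0 ± 3.57 to 157 ± 4.35 CPM. Adjusted p for these 12 genes ran from 1.90e-11 for NDRG1 to 7.95e-06 for COL6A2.

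By the naming rule the largest falls in shHES1, apart from XIST, were smaller than the largest rises. The neurosecretory protein gene VGF fell by 0.88 ± 0.06 on the log2 scale, from 153 ± 9.37 to 83.2 ± 5.21 CPM, and CCNG1, a p53 target, fell by 0.74 ± 0.04, from 64.3 ± 3.28 to 38.6 ± 0.508 CPM. LRP11 fell by 0.87 ± 0.16, the insulin-like growth factor binding gene IGFBP7 by 0.83 ± 0.08, and the signalling adaptor gene PIK3AP1 by 0.83 ± 0.11. NPR1, the atrial natriuretic peptide receptor, fell by 0.81 ± 0.12, and MARCHF4, S100P, ELOVL2, ASRGL1 and CYP4F3 fell by 0.80 ± 0.09, 0.78 ± 0.17, 0.75 ± 0.12, 0.74 ± 0.10 and 0.74 ± 0.11. XIST, the long noncoding RNA of X inactivation, was at a mean of 24.1 ± 1.16 CPM in shCtrl and had 0 counts in both shHES groups. Against a floor of 3 counts over the group, it was at least 643-fold lower in shHES1 and at least 560-fold lower in shHES4. XIST is among the transcripts found nearly only in shCtrl that are described under other observations. These values do not tell a loss in the shHES groups from an outside source of XIST in shCtrl.

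**Figure D2:**
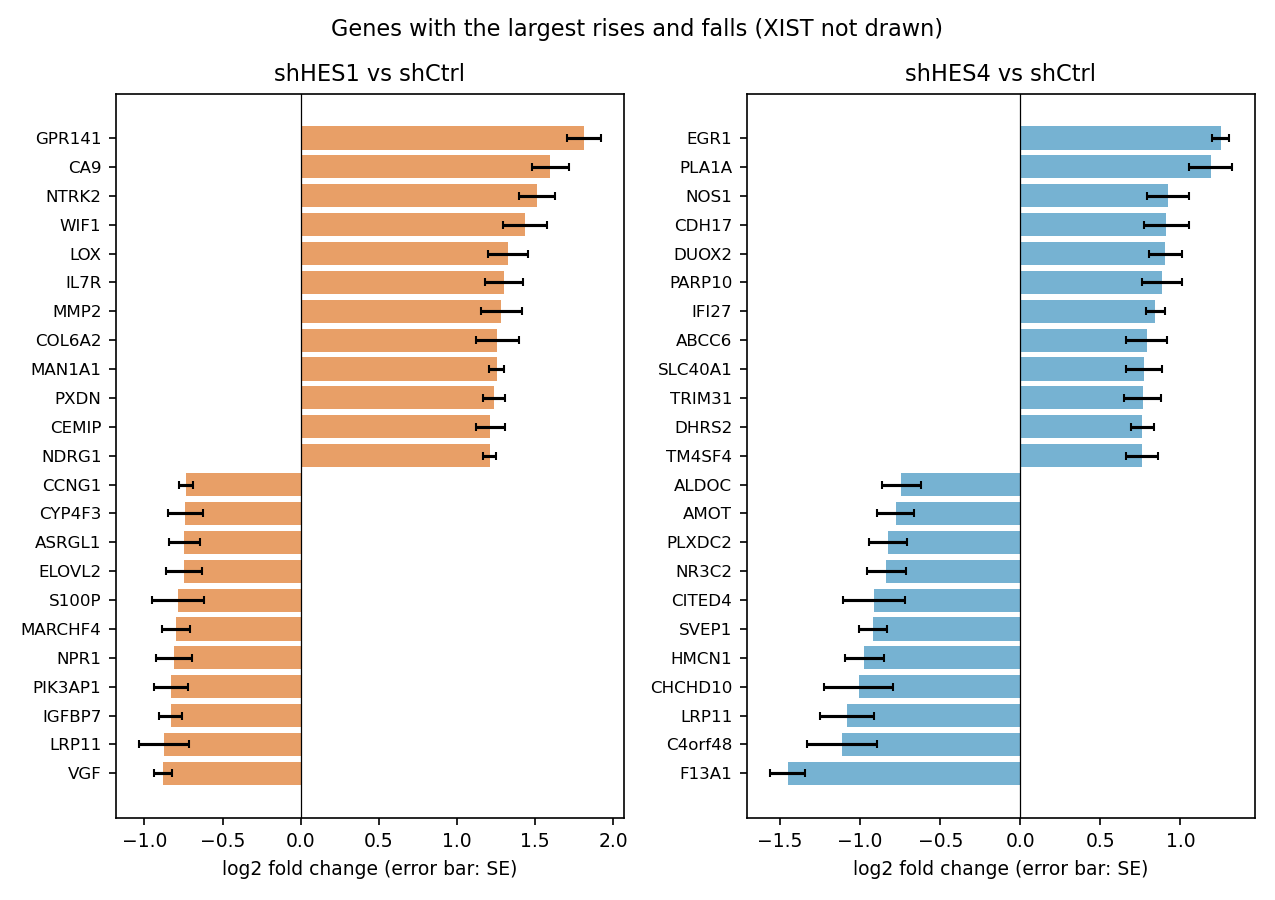
Log2 fold change against shCtrl (horizontal axis, bars, with SE) of the genes with the largest rises and falls in the libraries labelled shHES1 (left) and shHES4 (right), n = 3 per group. The rises reach 1.81 for GPR141 in shHES1 and 1.25 for EGR1 in shHES4, and the falls drawn reach -0.88 for VGF and -1.45 for F13A1; XIST, at 0 counts in both shHES groups, is not drawn.

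Gene lists fixed before the data were examined placed these genes in groups. Of 33 tested hypoxia and glycolysis genes, 10 were higher and 4 lower in shHES1 (14 and 7 adjusted over the list alone), including ANGPTL4 at 0.88 ± 0.04, EGLN3 at 1.02 ± 0.06 and SLC2A3, a glucose transporter gene, at 0.42 ± 0.03. The list was called higher (camera adjusted p = 9.82e-04, and adjusted p = 0.0669 with an estimated correlation). Of 19 tested mesenchymal genes, 10 rose and 1 fell, as they did adjusted over the list alone, with COL5A1 at 0.56 ± 0.04, fibronectin (FN1) at 0.46 ± 0.03 and N-cadherin (CDH2) at 0.44 ± 0.04. The median was 0.34 and the camera adjusted p 5.39e-06, with an adjusted p of 0.256 with an estimated correlation. Of 20 tested TGF-beta target genes, 11 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 8.80e-07, and adjusted p = 0.0668 with an estimated correlation), with TGFB2 at 0.56 ± 0.04, LTBP1 at 0.55 ± 0.04 and TGFBI at 0.34 ± 0.03. Of 28 tested NF-kB and inflammatory genes, 8 rose and none fell (10 and 0 adjusted over the list alone), among them complement C3 at 0.42 ± 0.03, LCN2 at 0.51 ± 0.05, CXCL1 at 0.29 ± 0.03 and TNFAIP3 at 0.32 ± 0.04 (camera adjusted p = 5.32e-06, and adjusted p = 0.0479 with an estimated correlation). YAP/TAZ target genes were called higher, with 6 of 23 up and 3 down (10 and 4 adjusted over the list alone; camera adjusted p = 0.0253, and adjusted p = 0.357 with an estimated correlation). IGFBP3 rose by 1.00 ± 0.05 and ANKRD1 by 1.19 ± 0.14, while PTPN14 fell by 0.51 ± 0.05, and the list lost its call without shCtrl replicate 1 (camera adjusted p = 0.0682), with a mean of at least 5 CPM (0.170) and with the 6 libraries compared alone (0.0691). Its camera adjusted p ranged from 0.00877 to 0.170 over the alternatives to the count model and the samples.

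Other lists fell in shHES1. Of 25 tested G1/S genes, which serve DNA replication, 15 were lower and none higher (21 and 0 adjusted over the list alone), with MCM2 at -0.26 ± 0.04, CDC6 at -0.25 ± 0.04, PCNA at -0.21 ± 0.03 and RRM2 at -0.20 ± 0.03. The camera adjusted p was 1.67e-11, and the adjusted p 0.0192 with an estimated correlation. The G2/M list, with 25 tested genes, was not called, at a median of -0.01 (camera adjusted p = 0.501). Of 28 tested NRF2 target genes, the antioxidant program that KEAP1 mutation keeps active in A549, 18 fell and 1 rose, as they did adjusted over the list alone (camera adjusted p = 3.38e-09, and adjusted p = 0.0614 with an estimated correlation). The ferritin light chain gene FTL was at -0.40 ± 0.02, GPX2 at -0.61 ± 0.05, AKR1B10 at -0.32 ± 0.03 and ALDH3A1 at -0.28 ± 0.03. Of 30 tested interferon response genes, 14 fell and none rose (18 and 0 adjusted over the list alone), with OAS1 at -0.37 ± 0.03, OAS2 at -0.39 ± 0.04, OAS3 at -0.25 ± 0.03 and MX1 at -0.25 ± 0.03 (camera adjusted p = 2.12e-07, and adjusted p = 0.0192 with an estimated correlation). Of 17 tested replication-dependent histone genes, 4 fell (5 adjusted over the list alone), including H2BC12 at -0.46 ± 0.03 and H1-2 at -0.50 ± 0.05; histone genes are near-identical copies between which reads can be split, so single members are uncertain. The camera adjusted p was 0.00375, and the adjusted p 0.0819 with an estimated correlation. Among 22 immediate early and heat shock genes, 2 rose and 6 fell (2 and 8 adjusted over the list alone), with HSPA1B at -0.32 ± 0.03, HSPA1A at -0.23 ± 0.04, NR4A1 at -0.31 ± 0.04 and EGR1 at 0.48 ± 0.06. This list was called lower (camera adjusted p = 0.0366, and adjusted p = 0.349 with an estimated correlation), and its call ended without shCtrl replicate 3, shHES1 replicate 1 or shHES1 replicate 2 (camera adjusted p = 0.0855, 0.0761 and 0.0584). It also ended with the replicate number as a block, total counts, the 6 libraries compared alone or the GC and length correction (camera adjusted p = 0.0739, 0.0515, 0.0566 and 0.0719), over a range from 0.0260 to 0.0855.

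Small falls were also called for cytosolic ribosomal protein, oxidative phosphorylation and ribosome biogenesis genes, with medians of -0.06, -0.08 and -0.06. Their camera adjusted p were 1.43e-04, 7.30e-05 and 0.00207, and the adjusted p with an estimated correlation were 0.697, 0.539 and 0.0668. Few single members passed, 4 of 61, 2 of 48 and 2 of 24 (1, 1 and 2 adjusted over the list alone), all of them lower. Among 7 tested CDK inhibitor genes, CDKN1B rose by 0.30 ± 0.05, and the list was not called (camera adjusted p = 0.879, where its median was 0.03 and its mean -0.49). CDKN2A, also in this list, had 61 counts over the shCtrl libraries against 4 in shHES1 and 1 in shHES4.

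In all, 1644 of 16903 genes differed between shHES1 and shCtrl, 887 higher and 757 lower, and 110 of them by at least 2-fold (92 higher and 18 lower). The 2-fold count was 208 without a filter on low counts and 22 with a mean of at least 5 CPM. The median fold among called genes was 1.20. The values of the 2 groups did not overlap for 27.6% of the genes tested, where chance gives 10%. Among the called genes the share was 99.1%, which follows largely from the calling and is no separate support. The count was 1084 without shHES1 replicate 2, and scaling by total counts alone called 1723 genes, 1174 of them higher, while the GC and length correction called 1978, 921 of them higher.

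The libraries labelled shHES4 differed from shCtrl most clearly in the interferon response. Of 30 tested interferon response genes, 28 were higher and none lower (30 and 0 adjusted over the list alone), with a median log2 fold change of 0.38. MX1 and OAS1 both rose by 0.44 ± 0.03, IFIT2 by 0.46 ± 0.03 and IFIT3 by 0.39 ± 0.03, and IFI27 went from 49.9 ± 5.23 to 89.5 ± 3.48 CPM. The list had a camera adjusted p of 2.45e-35, and an adjusted p of 4.82e-04 with an estimated correlation. PARP10, an interferon-inducible ADP-ribosyltransferase gene, rose by 0.89 ± 0.13.

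In shHES4 EGR1, a transcription factor gene induced within minutes by growth factors, rose by 1.25 ± 0.06, from 25.4 ± 1.39 to 60.5 ± 3.44 CPM, the largest rise by the naming rule. FOS rose by 0.71 ± 0.05, FOSB by 1.54 ± 0.16 and JUNB by 0.34 ± 0.04, while the heat shock gene HSPA1B fell by 0.32 ± 0.03. In the immediate early and heat shock list 9 of 22 genes rose and 4 fell (9 and 5 adjusted over the list alone; camera adjusted p = 0.0145, and adjusted p = 0.272 with an estimated correlation). This call ended in a correction for GC content and length (camera adjusted p = 0.0697, the highest over the alternatives, the lowest being 0.00755). Of 24 tested MAPK output genes, 9 rose and none fell (12 and 0 adjusted over the list alone), among them AREG, an epidermal growth factor receptor ligand gene, at 0.47 ± 0.04 and JUN at 0.31 ± 0.04; EGR1 and FOS belong to both lists. The camera adjusted p was 1.20e-07, and the adjusted p 0.0569 with an estimated correlation. Of 25 tested p53 target genes, 7 rose and none fell (10 and 0 adjusted over the list alone; camera adjusted p = 3.07e-07, and adjusted p = 0.0337 with an estimated correlation), with CDKN1A at 0.29 ± 0.03, MDM2 at 0.27 ± 0.04, FAS at 0.38 ± 0.06 and TNFRSF10B at 0.18 ± 0.03. NF-kB and inflammatory genes rose in 7 of 28 cases and fell in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 8.91e-04, and adjusted p = 0.0750 with an estimated correlation). LCN2 was at 0.53 ± 0.05, ICAM1 at 0.36 ± 0.05 and NFKB2 at 0.23 ± 0.03, and the chemokine gene CXCL1 fell by 0.19 ± 0.03. Of 25 apoptosis regulators 4 rose (5 adjusted over the list alone), with MCL1 at 0.18 ± 0.03 and PMAIP1 at 0.20 ± 0.04 (camera adjusted p = 0.00873, and adjusted p = 0.0819 with an estimated correlation). Of 24 integrins, laminins and matrix receptors 5 rose (9 higher and 1 lower adjusted over the list alone), with ITGA5 at 0.28 ± 0.03 and ITGB3 at 0.47 ± 0.07 (camera adjusted p = 9.82e-04, and adjusted p = 0.203 with an estimated correlation).

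Hypoxia and glycolysis genes were lower in shHES4. Of 33 tested, 9 fell and none rose (16 and 0 adjusted over the list alone), with SLC2A3 at -0.33 ± 0.03, GPI at -0.16 ± 0.03, PFKFB3 at -0.19 ± 0.03 and the aldolase gene ALDOC at -0.74 ± 0.12. The camera adjusted p was 1.36e-06, and the adjusted p 0.0321 with an estimated correlation. Of 25 tested G2/M genes 6 fell and none rose (13 and 0 adjusted over the list alone), with CENPF at -0.22 ± 0.04 and TOP2A at -0.14 ± 0.03 (camera adjusted p = 2.33e-06, and adjusted p = 0.112 with an estimated correlation). Cholesterol synthesis genes were called lower, with 3 of 24 down and 1 up (10 and 2 adjusted over the list alone; camera adjusted p = 0.00344, and adjusted p = 0.0669 with an estimated correlation). NRF2 target genes moved both ways, with 10 of 28 lower and 1 higher (10 and 3 adjusted over the list alone). AKR1C2 fell by 0.27 ± 0.03 and AKR1C3 by 0.21 ± 0.03, while GPX2 rose by 0.41 ± 0.05. The list had a camera adjusted p of 0.0232, and an adjusted p of 0.357 with an estimated correlation, and lost its call without shCtrl replicate 2 (camera adjusted p = 0.0823) and without shHES4 replicate 3 (camera adjusted p = 0.0721), over a range from 0.00393 to 0.0823. Histone genes rose in 2 of 17 cases, H2BC12 by 0.17 ± 0.03 and H2AC6 by 0.22 ± 0.04 (3 adjusted over the list alone; camera adjusted p = 0.0232, and adjusted p = 0.158 with an estimated correlation). That call ended without shCtrl replicate 1 (camera adjusted p = 0.0504), without shHES4 replicate 1 (camera adjusted p = 0.0934) and in the GC and length correction (camera adjusted p = 0.0549), over a range from 8.41e-04 to 0.0934. Mitochondrially encoded genes were called lower, with 3 of 15 down (7 adjusted over the list alone) and MT-RNR2 at -0.33 ± 0.03 (camera adjusted p = 0.00192, and adjusted p = 0.539 with an estimated correlation), and the call ended without shCtrl replicate 3 (camera adjusted p = 0.0747, range 1.11e-04 to 0.0747). Oxidative phosphorylation genes, at a median of -0.04, were also called lower (camera adjusted p = 0.0212, and adjusted p = 0.733 with an estimated correlation). That call ended without shCtrl replicate 1, shCtrl replicate 2 or shHES4 replicate 3 (camera adjusted p = 0.294, 0.221 and 0.322, range 9.36e-07 to 0.322). G1/S genes were near the threshold (1 of 25 lower and 0 adjusted over the list alone, median -0.04, camera adjusted p = 0.0464, and adjusted p = 0.292 with an estimated correlation). Their call ended without shCtrl replicate 1 or 3, shHES1 replicate 1 or 2, or shHES4 replicate 2 or 3 (camera adjusted p = 0.0504, 0.0947, 0.0507, 0.0521, 0.0970 and 0.106, range 0.0128 to 0.106), and with total counts, the 6 libraries compared alone or a mean of at least 5 CPM (camera adjusted p = 0.0659, 0.0613 and 0.0717).

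Among the single genes with the largest rises in shHES4, the phospholipase gene PLA1A rose by 1.19 ± 0.13, the neuronal nitric oxide synthase gene NOS1 by 0.92 ± 0.13, the intestinal cadherin gene CDH17 by 0.91 ± 0.14 and the dual oxidase gene DUOX2 by 0.91 ± 0.10. The iron exporter gene SLC40A1 rose by 0.77 ± 0.12, and ABCC6, TRIM31, DHRS2 and TM4SF4 by 0.79 ± 0.13, 0.76 ± 0.12, 0.76 ± 0.07 and 0.76 ± 0.10. Among the falls, F13A1, encoding the coagulation factor XIII A chain, fell by 1.45 ± 0.11, from 10.7 ± 0.553 to 3.93 ± 0.601 CPM. LRP11 fell by 1.08 ± 0.17, the matrix gene HMCN1 by 0.98 ± 0.12, SVEP1 by 0.92 ± 0.09 and the mineralocorticoid receptor gene NR3C2 by 0.84 ± 0.12. PLXDC2 and AMOT fell by 0.83 ± 0.12 and 0.78 ± 0.12. C4orf48, CHCHD10 and CITED4 fell by 1.11 ± 0.22, 1.01 ± 0.21 and 0.91 ± 0.19, and their longest transcripts have GC contents of 73.2%, 68.4% and 73.5%, near the 73.9% of HES4. The call for CITED4 ended without shHES4 replicate 3 (adjusted p = 0.0549, the highest of its alternatives).

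Across all genes, 1004 differed between shHES4 and shCtrl, 547 higher and 457 lower, and 60 of them by at least 2-fold (34 higher and 26 lower). The 2-fold count was 150 without a filter, 7 with a mean of at least 5 CPM and 38 in DESeq2. The median fold among called genes was 1.21. The groups did not overlap for 22.4% of tested genes, where chance gives 10%, and for 98.8% of called genes, which follows largely from the calling. The number of lower genes was 304 without shHES4 replicate 3. The share of higher genes was 54.5%, against 46.5% without a filter on low counts and 59.5% with total counts alone.

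**Figure D3:**
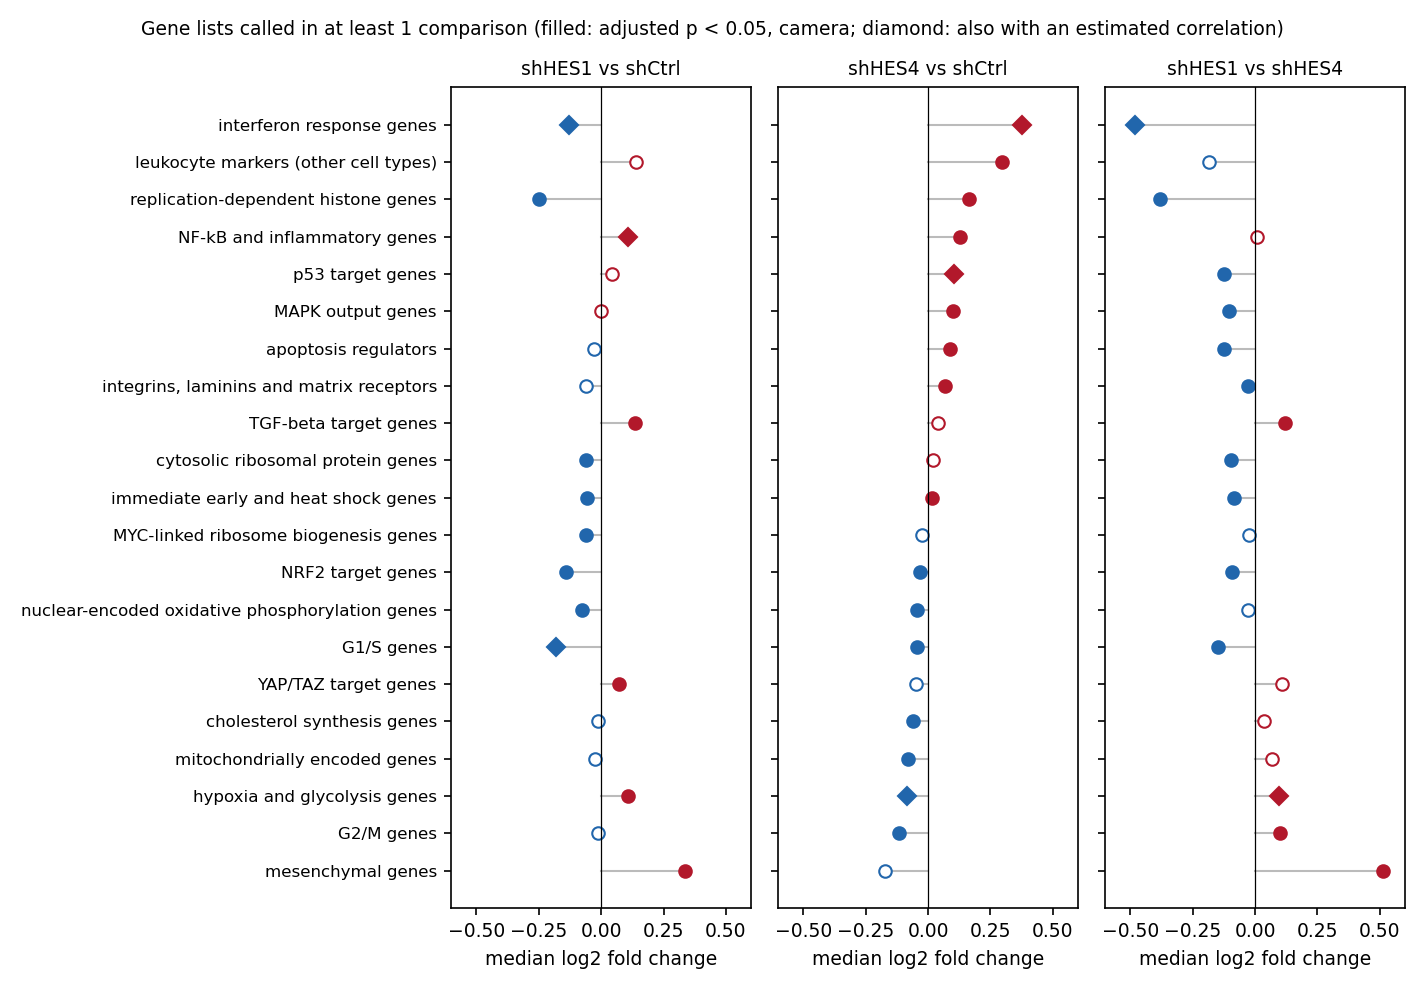
Median log2 fold change (horizontal axis) of the tested members of each gene list that was called in at least 1 of the 3 comparisons; red is above 0 and blue below 0, filled symbols have a camera adjusted p under 0.05 and diamonds also with an estimated correlation. Interferon response genes lie at -0.13 in shHES1, 0.38 in shHES4 and -0.48 in the direct comparison, and mesenchymal genes at 0.34, -0.17 and 0.51, of which the value in shHES4 was not called.

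The shHES groups were compared directly, without the shared controls. All 30 tested interferon response genes were lower in the libraries labelled shHES1 than in those labelled shHES4, also when adjusted over the list alone, with a median of -0.48 (camera adjusted p = 3.26e-32, and adjusted p = 4.82e-04 with an estimated correlation). OAS1 differed by -0.82 ± 0.03, MX1 by -0.68 ± 0.03 and IFI27 by -1.15 ± 0.06. Hypoxia and glycolysis genes were higher in shHES1 in 18 of 33 cases and lower in none (18 and 2 adjusted over the list alone), with NDRG1 at 1.46 ± 0.04, SLC2A3 at 0.75 ± 0.03 and EGLN3 at 1.24 ± 0.07 (camera adjusted p = 8.84e-09, and adjusted p = 0.0192 with an estimated correlation). Mesenchymal genes were higher in 10 of 19 cases and lower in 1 (11 and 2 adjusted over the list alone), with FN1 at 0.63 ± 0.04 and CDH2 at 0.62 ± 0.04 (camera adjusted p = 2.22e-05, and adjusted p = 0.274 with an estimated correlation). MAPK output genes were lower in 13 of 24 cases and higher in 2 (13 and 3 adjusted over the list alone), with EREG at -0.70 ± 0.05, AREG at -0.64 ± 0.04 and EGR1 at -0.77 ± 0.05 (camera adjusted p = 1.73e-04, and adjusted p = 0.101 with an estimated correlation). Of 25 p53 target genes 10 were lower and none higher, as adjusted over the list alone, with CCNG1 at -0.79 ± 0.04, GDF15 at -0.50 ± 0.05 and MDM2 at -0.31 ± 0.04 (camera adjusted p = 1.09e-04, and adjusted p = 0.0654 with an estimated correlation). G1/S genes were lower in 13 of 25 cases (16 adjusted over the list alone; camera adjusted p = 1.04e-05, and adjusted p = 0.0614 with an estimated correlation), and G2/M genes higher in 6 of 25 (10 adjusted over the list alone; camera adjusted p = 9.82e-04, and adjusted p = 0.272 with an estimated correlation).

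Further lists were called in the direct comparison. Histone genes were lower in shHES1 in 7 of 17 cases (9 adjusted over the list alone), with H2BC12 at -0.63 ± 0.03 (camera adjusted p = 3.52e-04, and adjusted p = 0.0614 with an estimated correlation). Immediate early and heat shock genes were lower in 11 of 22 cases and higher in 1, as adjusted over the list alone, with NR4A1 at -0.63 ± 0.04 and FOS at -0.66 ± 0.04 (camera adjusted p = 1.76e-05, and adjusted p = 0.0750 with an estimated correlation). NRF2 target genes were lower in 14 of 28 cases and higher in 4 (15 and 5 adjusted over the list alone), with GPX2 at -1.02 ± 0.05 and AKR1C3 at 0.27 ± 0.03 (camera adjusted p = 9.36e-04, and adjusted p = 0.203 with an estimated correlation). TGF-beta target genes were higher in 10 of 20 cases and lower in 3, as adjusted over the list alone, with TGFB2 at 0.76 ± 0.04 (camera adjusted p = 0.00693, and adjusted p = 0.267 with an estimated correlation). Ribosomal protein genes were lower in 21 of 61 cases (28 adjusted over the list alone), at a median of -0.10 (camera adjusted p = 2.33e-06, and adjusted p = 0.624 with an estimated correlation). Apoptosis regulators were lower in 6 of 25 cases and higher in 1, as adjusted over the list alone, with CFLAR at -0.34 ± 0.04 (camera adjusted p = 0.0208, and adjusted p = 0.112 with an estimated correlation). Integrins, laminins and matrix receptors were lower in 7 of 24 cases and higher in 1 (8 and 1 adjusted over the list alone), with LAMB3 at -0.40 ± 0.04 and ITGB3 at 0.61 ± 0.07 (camera adjusted p = 0.0208, and adjusted p = 0.350 with an estimated correlation). With a mean of at least 5 CPM the apoptosis and integrin calls ended (camera adjusted p = 0.0669 and 0.0749), as did the integrin call without shHES4 replicate 3 (0.0785). Their ranges were 0.0132 to 0.0669 and 5.57e-04 to 0.0785.

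Single genes separated the shHES groups further. GPR141 was higher in shHES1 by 2.12 ± 0.11 on the log2 scale, NTRK2 by 2.07 ± 0.12, the membrane skeleton gene EPB41L3 by 1.97 ± 0.15, LOX by 1.86 ± 0.14, F13A1 by 1.77 ± 0.11 and HMCN1 by 1.71 ± 0.12. NOS1 stood at 2.06 ± 0.267 CPM in shHES1 and 7.98 ± 0.825 CPM in shHES4, and DHRS2 at 8.32 ± 0.169 and 22.6 ± 0.711 CPM. TM4SF20, ABCC6 and S100P were at -1.30 ± 0.10, -1.24 ± 0.13 and -1.16 ± 0.16. The direct comparison called 2546 genes, 1253 higher and 1293 lower in shHES1, 210 of them by at least 2-fold (132 and 78), a number that was 43 with a mean of at least 5 CPM. The share of higher genes was 49.2%, against 58.7% with total counts alone and 46.4% in the GC and length correction. The median fold among called genes was 1.21. The groups did not overlap for 33.0% of tested genes, where chance gives 10%, and for 98.9% of called genes, which follows largely from the calling.

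Genes changed in both shHES groups were compared next. DUOX2, which produces hydrogen peroxide at epithelial surfaces, rose in shHES1 by 0.76 ± 0.10 and in shHES4 by 0.91 ± 0.10. The serpin gene SERPINB3 rose by 1.06 ± 0.06 and 0.63 ± 0.06, keratin 19 (KRT19) by 0.73 ± 0.05 and 0.54 ± 0.06, the adhesion gene CEACAM1 by 0.53 ± 0.05 and 0.59 ± 0.05, and LCN2 by 0.51 ± 0.05 and 0.53 ± 0.05. LRP11 and SVEP1 fell in both, as did EBPL, by 0.64 ± 0.12 in each, and CTU1, by 0.61 ± 0.13 and 0.65 ± 0.13. In all, 126 genes were higher in both and 89 lower in both, where independent lists of these sizes would share 28.7 and 20.5. In the opposite sense, 58 genes were higher in shHES1 and lower in shHES4 (24.0 for independent lists) and 72 lower in shHES1 and higher in shHES4 (24.5 for independent lists). The figures for independent lists treat every gene as equally likely to be called. Calls in both groups exceeded them in either sense, so an excess over them does not by itself show a shared response. Of the 1299 genes called in shHES1 and not in shHES4, 867 differed in the direct test, and of the 659 called in shHES4 and not in shHES1, 434 did.

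Both comparisons share the shCtrl libraries, which adds agreement by chance. In 20 simulated data sets of unchanged groups at most 1 gene was called in both in the same direction. With no group changed few genes can be called at all. This number therefore does not measure how many same-direction calls the shared controls add to the real data. Over the 11584 genes with at least 5 CPM, without XIST, the covariance of the log2 fold changes was 0.00411 against 0.00307 in the simulations, and Pearson's r across genes, which are not independent replicates, was 0.185 against 0.503. Over all tested genes without XIST the covariance was 0.0450 against 0.0221 and r was 0.422 against 0.493, so these values depend on the low genes. The 3 controls are too few to split, so part of the excess may come from the shared controls. That covers chance and any difference common to all 3 shCtrl libraries, which would appear in both comparisons in the same direction. The number called in both in the same direction was 215, and it was 136 without shCtrl replicate 2, 135 without shHES1 replicate 3, 243 without shCtrl replicate 1 and 341 without a filter on low counts.

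**Figure D4:**
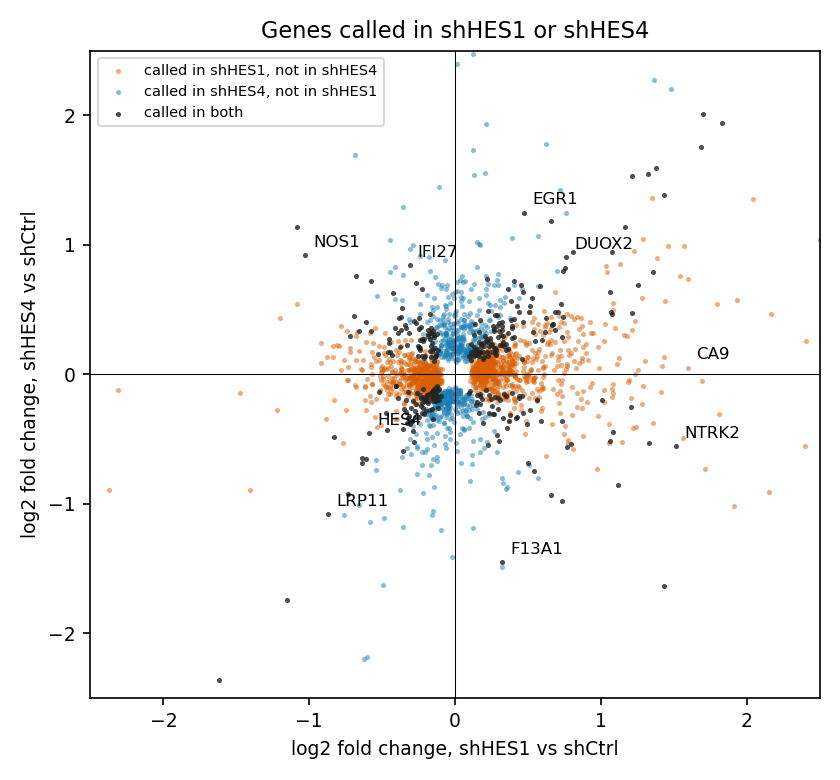
Log2 fold change against shCtrl in the libraries labelled shHES1 (horizontal axis) and shHES4 (vertical axis) for the genes called in either, coloured by where they were called; XIST is left out, and 20 of the 2302 genes lie outside the axis limit of 2.5. Of the genes called in both (black), 215 moved in the same direction, XIST included, and 130 in opposite directions.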

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

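A set of 4 gene lists was called by camera in opposite directions against shCtrl in the 2 shHES groups. The direct test between the groups called each of them with the preset correlation. The immediate early and heat shock list was mixed in both groups. In shHES1 2 members rose and 6 fell (median -0.055), and in shHES4 9 rose and 4 fell (median 0.014). In the direct test the interferon and hypoxia lists kept their call (adjusted p = 4.82e-04 and 0.0192 with an estimated correlation) and the histone and immediate early lists lost it (adjusted p = 0.0614 and 0.0750 with an estimated correlation). Against shCtrl, calls were also lost for hypoxia in shHES1 (adjusted p = 0.0669 with an estimated correlation), for histone genes in shHES1 and shHES4 (0.0819 and 0.158) and for immediate early genes in both (0.349 and 0.272). The estimated correlations of the hypoxia and histone lists were 0.00939 and 0.00767, below the preset 0.01. A larger correlation between members was therefore not what ended the hypoxia and histone calls. The tests of GC content, depth and control libraries below were set out before their results were seen, and the correction and the thinning they use were chosen after the differences between the groups were known. The median log2 difference between the libraries labelled shHES1 and shHES4 was -0.48 for interferon response genes, 0.10 for hypoxia and glycolysis genes, -0.38 for replication-dependent histone genes and -0.083 for immediate early and heat shock genes.

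The interferon response genes differed in all 30 tested members in the direct comparison. The values argue against a GC content or transcript length trend as the cause of this difference. After the correction for both, 30 of the 30 members were lower in shHES1. At equal depth 30 were too, but totals of 22.8 to 27.6 M were already close, so thinning could change little. The direct comparison does not compare shCtrl levels, so leaving out controls bears on shHES4 against shCtrl only. There, without any 1 of the shCtrl libraries, at least 26 members were called higher in shHES4. That argues against 1 odd control library, but not against a fault shared by all 3. Over all alternatives, 29 or 30 members were lower in shHES1 than in shHES4. A candidate explanation is a different interferon tone of the 2 cell populations, which may follow from HES1 or HES4, from the hairpins or the vector, or from how each population was made; each group has 1 hairpin label, so these stay open and untested.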

How the results depend on the processing

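The GC and length correction and the equal-depth thinning were chosen after seeing the data, and the other alternatives before. The number of genes called stayed within 1.5 times its value in each alternative that kept the 3 replicates, with 1334 to 1978 for shHES1 against shCtrl, 773 to 1474 for shHES4 against shCtrl and 2022 to 2871 in the direct comparison. Leaving out 1 library gave 1084 to 1800, 682 to 1015 and 1775 to 2936, the lowest of the first without shHES1 replicate 2. Lower genes then ranged over 476 to 878 in shHES1 (476 and 499 without shHES1 replicates 2 and 3) and 304 to 509 in shHES4 (304 without shHES4 replicate 3). They rose to 878 without shCtrl replicate 3 and to 509 without shCtrl replicate 1, and the cause was not tested. Genes changed at least 2-fold depended on the filter, since most are low: without a filter they numbered 208 and 150 in shHES1 and shHES4, and with a mean of at least 5 CPM 22, 7 and, in the direct comparison, 43. DESeq2 gave 38 in shHES4, and the cause was not tested. Without a filter 788 genes were lower in shHES4 and 341 changed in both shHES groups in the same direction. That overlap ranged over 135 to 243 with 1 library left out. Scaling by total counts alone called 1174 higher genes of 1723 in shHES1, where the share of higher genes was 68.1% against 54.0%, and moved the median of all genes to 0.02. The balance turned the other way, to 46.6%, in the GC and length correction, with 921 higher and 1057 lower genes, and stood at 49.8% without shCtrl replicate 1.

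HES1 in shHES1 was not called in any alternative, at 0.19 to 0.23, and at 0.09 to 0.34 with 1 library left out. HES4 in shHES4 ranged over -0.47 to -0.31, and over -0.56 to -0.37 with 1 library left out, where its call ended at -0.42 without shHES4 replicate 2 and -0.40 without shHES4 replicate 3. With an estimated correlation 3, 3 and 2 gene lists were called in the 3 comparisons. With fry, which does not compare a list with other genes, 23 were called in the direct comparison and 6 list calls ended: ribosomal protein genes in shHES1 and in the direct comparison, oxidative phosphorylation genes in both shHES groups, and mitochondrially encoded genes and leukocyte markers in shHES4. Leaving out 1 library gave 12 to 14, 13 to 16 and 14 to 16 lists. Besides HES4 in shHES4, the genes named in the text had 313 calls in the 3 comparisons, and 22 of them ended in at least 1 alternative, of which the text gives those of MAML2 in shHES1 and of SPEN and CITED4 in shHES4. With 1 library left out, calls ended in 85 cases and stayed in 2732. Of these calls 8 ended with the 6 libraries compared alone, 5 with the replicate block, 4 each in DESeq2 and limma-voom, 3 with total counts, and 1 each at equal depth and in the GC and length correction. None of these genes or lists was called in the opposite direction. A call on a gene without a value in an alternative was not followed there and counts as neither ended nor kept. With a mean of at least 5 CPM 288 of the 313 calls could be followed, and all 288 stayed. In DESeq2 305 stayed beside the 4 that ended.

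Replicate numbers are shared between the groups, but same-numbered libraries did not deviate together, with correlations of -0.05 to 0.05 against -0.04 to 0.06 for other pairs. With the replicate number as a block, 1443, 850 and 2297 genes were called, HES4 in shHES4 stood at -0.46, and the list call it ended was that of immediate early and heat shock genes in shHES1. Depth limits genes near the filter: HES2 had 36 counts over the 3 shCtrl libraries.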

Other observations

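Tests chosen only after the result was seen are the exchange of labels, the share of IRS4 in 1 library and the counts of genes found in 1 group only, and the GC and length correction was also added then. The neuroendocrine granin gene CHGB rose by 0.36 ± 0.05 on the log2 scale in shHES1 and by 0.66 ± 0.05 in shHES4, and the decarboxylase gene DDC rose by 0.76 ± 0.16 in shHES4. The neuronal enolase gene ENO2 rose by 0.25 ± 0.04 in shHES1, but it also belongs to the hypoxia and glycolysis list, which was called higher there. Of 9 tested proneural and neuroendocrine genes 2 rose in each shHES group (3 in shHES1 and 2 in shHES4 adjusted over the list alone), and the list was not called in either (camera adjusted p = 0.165 and 0.195). Of 17 tested epithelial genes 6 fell and 1 rose in shHES1 (6 and 2 adjusted over the list alone), with KRT18, CLDN1 and KRT8 lower by 0.29 ± 0.03, 0.29 ± 0.05 and 0.14 ± 0.02 and KRT19 higher, and 3 rose and none fell in shHES4, also adjusted over the list alone. The list was not called in either (camera adjusted p = 0.138 and 0.169).

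The lists of other cell types gave little. Leukocyte markers were called higher in shHES4 (camera adjusted p = 0.0294, and adjusted p = 0.359 with an estimated correlation), with a median of 0.30 over 5 tested genes. The lysosomal gene CD68, at 0.30 ± 0.05, was the 1 member that passed the test on its own. That call ended without shCtrl replicate 1 (camera adjusted p = 0.106), shHES4 replicate 2 (camera adjusted p = 0.122) or shHES4 replicate 3 (camera adjusted p = 0.0556), and in the GC and length correction (camera adjusted p = 0.0605), over a range from 0.00647 to 0.122. Fibroblast and endothelial markers were not called in shHES1 or shHES4 (camera adjusted p = 0.138 and 0.623), nor were kidney cell line markers (camera adjusted p = 0.490 and 0.784). The 6 tested fibroblast and endothelial markers had medians of 0.29 in shHES1 and -0.03 in shHES4. In the direct comparison their median was 0.47, and they were not called there either (camera adjusted p = 0.144).

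HES1 was not lower in the libraries labelled shHES1, and HES4 was lower in both shHES groups. Both falls of HES4 are measured against the same shCtrl libraries, which also hold the transcripts described in the next paragraph. The shHES groups did not differ detectably in HES4 (edgeR adjusted p = 0.456). A higher HES4 in shCtrl thus cannot be told apart from a fall in each shHES group. An exchange of labels between the shHES groups would place a fall of HES1 in the libraries labelled shHES4, where its log2 fold change was -0.033 ± 0.12 (SE). After the GC and length correction HES4 stood at -0.51 ± 0.07 in shHES1 and -0.31 ± 0.07 in shHES4, and 1.00% and 4.50% of the 200 genes nearest to it in GC content and length fell by as much (exact 95% intervals 0.121% to 3.57% and 2.08% to 8.37%). These 200 genes span GC contents of 62.1% to 74.5%, and HES4, at 73.9%, lies near the upper end, which limits them as a match. So a GC or length trend is argued against for shHES1, while in shHES4 HES4 was called after the correction (edgeR adjusted p = 0.0114) but moved from -0.46 ± 0.10 to within its spread of the bound of -0.3, so a trend stays open as part of the cause, as does an ordinary spread of such genes, since the interval in shHES4 includes 5%. A hairpin that acts on HES1 protein more than on its transcript, or a loss of its effect in the cells sequenced, may also account for HES1 and was not tested.

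Transcripts seen in shCtrl and nearly absent from both shHES groups form a second pattern. By a rule of at least 30 counts in a group, at least 5 in each of its libraries and at most 10% of that in each other group, 3 genes belonged to shCtrl, XIST, IRS4 and CDKN2A, and 2 to shHES1, ITM2A and PLPP4. IRS4 had 350 counts in shCtrl against 4 in shHES1 and 2 in shHES4, and at most 36.0% of them lay in 1 library, which argues against a single odd library. CDKN2A is known to be deleted in A549, so a candidate source is RNA of another cell line, such as HEK293, which is known to express IRS4 and CDKN2A and is used to package hairpin vectors; reads from other libraries of the same run may be the source too. Of 8 further HEK293 markers written down beforehand 2, SOX11 and TFAP2B, were under 0.5 CPM in both shHES groups. Of their 3 counts 0% lay in shCtrl, with an exact 95% interval that reaches 70.8%, too few to decide. A share of the counts present also cannot register counts that are missing. Both genes had 0 counts in shCtrl, but how many HEK293 RNA would bring beside the 350 of IRS4 was not measured here. The source therefore cannot be told apart. For IRS4 and XIST, genes switched on or off by chance when the populations were made stay open too. A deleted gene cannot be switched on, so this does not cover CDKN2A if the deletion holds in these cells. The lower of IRS4 and XIST had 350 counts in shCtrl and CDKN2A 61, against 53 for the highest gene found in shHES1 only, but these genes were picked for this pattern and counting error does not measure such switching, so the counts decide nothing. The other 6 HEK293 markers, such as INA at 98.4 CPM in shCtrl, are expressed in these cells anyway.

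Other splits of the 6 samples of each comparison into 3 and 3 gave at most 1 called gene, against 1644, 1004 and 2546 for the real groups. The 10 splits are too few for a share under 0.05.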
